A study of Homo sapiens with 4 samples.

How the data were processed

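The study profiled the genomic binding of c-Jun, a subunit of the AP-1 transcription factor, in cultured human lung fibroblasts. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sonicated and precipitated with an antibody, and sequencing adapters were inserted by Tn5 transposase while the DNA was still on the beads (ChIPmentation). The labels name 4 libraries: 2 c-Jun precipitations and 2 inputs, and do not say whether replicates came from separate cultures. The authors deposited 1 peak list for the series, on the human build hg38 per the submitters' processing notes. Each of its lines holds 3 columns, the chromosome, the start and the end of a peak. The list carries no height, fold enrichment, score, p-value or library name, so nothing in it can be traced to 1 library. The aligner, the peak caller, its threshold, the use of the inputs and any pooling of the replicates are not given in the sources used here. Every interval is 290 bp wide, so the width holds no information on the extent or strength of binding. The smallest distance between the centres of neighbouring peaks is 200 bp. Sequencing depth is unknown. A gene without a peak is one to which no listed interval was assigned, not one shown to be free of c-Jun. An interval close to such a gene can have been assigned to a nearer gene.

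Peaks were placed by their centres, and positions are given counting from 1. Only the 22 autosomes were used, since sex chromosomes of human donors are not reported. Gene names and positions came from a RefSeq gene table of assembly GRCh38.p14, whose chromosome coordinates are those of hg38. That table gives the start and end of a gene but no strand, exons or sequence. The comparison of promoters planned before the data were examined was therefore made with both ends of each protein-coding gene, and 5' and 3' ends were not told apart. UTRs, coding exons and introns were not separated, and a peak was assigned to genes by the body and its nearest edge in place of the planned nearest 5' end. The planned searches for AP-1 sites and other sequence motifs, the matching on GC content and the tests on a peak score were not run, because no genome sequence and no score were used here.

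The background was random placement. Peaks of each autosome were placed 1000 times at random on the same autosome, between its outermost genes or peaks, leaving out stretches of over 1 Mb with neither a gene nor a peak, such as centromeres. The share of peaks in a class was compared with these placements by a two-sided permutation p, whose smallest possible value is 0.001998. Settings that left out other stretches used 200 placements each, with a smallest p of 0.00995 before adjustment. Placements treat peaks as independent, although peaks were grouped. The error of a share is a jackknife standard error (SE) from leaving out each autosome in turn. Placement ignores GC content, mappability and chromatin state, and the input libraries could not be used as a background in its place.

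For genes, a peak was assigned to every protein-coding gene whose body held its centre, otherwise to the gene with the nearest edge up to 100 kb away. The part of the chromosome from which a gene could receive peaks is called its territory. The expected number of peaks of a gene is its territory times the peak density of its chromosome. Peaks per gene were also tested with a negative binomial model of 1 dispersion for all genes, with Benjamini-Hochberg adjustment over 19126 genes, a test added after the data were seen, as were the profile of distances to gene ends and the correlation of density with gene density. The 17 gene lists were fixed before the data were examined, as were the alternatives described as planned. They hold 491 entries, of which 488 were matched to autosomal protein-coding genes of the table. The number of list genes with at least 1 peak was compared with 10000 random lists of the same size, drawn within 20 bins of territory length. The p is a two-sided permutation p, adjusted over the 17 lists by the Benjamini-Hochberg method. These p-values describe 1 peak list, not replicate cultures. Neighbouring genes can share peaks, so list members are not fully independent.

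Genes were named by a rule fixed before the data were examined: the 20 genes with the most peaks, up to 4 members of each list with the most peaks, and 16 fixed genes. Ties within a list were broken by peaks near gene ends, then by symbol, so an unnamed member can have as many peaks as a named one. The 10 largest clusters of peaks, joined across gaps of up to 12 kb, were named by the same rule. Any other named gene was chosen after its values were seen. The fixed genes reported were JUN, JUNB, FOS, FOSL1, FOSL2, POU5F1, SOX2, NANOG, LIN28A, COL1A1, FN1, CDKN1A, TGFB1, CDH1 and EPCAM. Of the fixed genes and of the 20 genes with the most peaks, 1 each is not reported here.

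The functions were tested on simulated data. For the gene list comparison, the assignment equalled a plain search over all genes for 690 of 690 genes. Of 300 random lists, 2% passed an unadjusted p of 0.05. Lists whose bound share was raised 1.5-fold were recovered at the same unadjusted p in 39.7% of 340 simulations, and lists raised 2-fold in 88.5% of 340. The median ratios found were 1.42 and 1.74, and a raised share was capped at all genes bound. Bound status was drawn for each gene independently. Recovery under the adjusted p used for the lists was not simulated and cannot be higher. In the gene end comparison, the peaks counted at gene ends in a simulated list were 0.984 of the number planted there plus that expected by chance. The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Alternatives changed the window around gene ends, the gene set, the overlap rule, the assignment distance and rule, the matching of the lists, the statistic and the regions open to random placement.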

Results

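Binding of c-Jun was mapped in cultured human lung fibroblasts by chromatin immunoprecipitation followed by tagmentation. Fibroblasts are the connective tissue cells from which induced pluripotent cells are commonly made, and the study's title places AP-1, the factor that c-Jun is part of, at the control of that reprogramming. Libraries were made from 2 c-Jun precipitations and 2 inputs, and the authors deposited 1 list of peaks. The list held 18297 peaks, each 290 bp wide on hg38, of which 18068 lay on the autosomes. These covered 5240 kb, or 0.194% of the 2705 Mb open to random placement, at 6.68 peaks per Mb. The median distance between neighbouring peaks was 58.2 kb, with quartiles of 18.8 and 162 kb. No value per library was used, so the spread between the replicates is unknown and no c-Jun library could be set against an input. The comparisons below ask where the listed sites lie in the genome and near which genes.

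The first question was where in relation to genes c-Jun was bound. Most peaks lay away from gene ends: 460 peaks, 2.55% ± 0.178 (jackknife SE over 22 autosomes), lay within 1 kb of either end of a protein-coding gene. Random placement gave 2.48% (95% range 2.24 to 2.70), a ratio of 1.03 that did not pass (two-sided permutation p = 0.587). Protein-coding gene bodies beyond those windows held 9196 peaks, 50.9% ± 0.862 against 43.2% at random (ratio 1.18, adjusted permutation p = 0.00599). Regions over 100 kb from any protein-coding gene and outside other annotated genes held 12.3% ± 0.841 against 19.5% at random (ratio 0.63, adjusted permutation p = 0.00599). The size of both differences depended on the regions open to placement. With stretches over 200 kb left out the ratios were 1.09 for gene bodies and 0.872 for the distant regions. With no stretch left out they were 1.24 and 0.521, and all of these passed the threshold. Leaving out more stretches with neither a gene nor a peak raises the random share inside genes by construction, so a lower ratio there follows from the setting. Other annotated genes held 14.2% ± 0.543 against 14.5% (adjusted permutation p = 0.187). With stretches over 200 kb left out their ratio fell to 0.902 (adjusted permutation p = 0.0149), a shift whose direction that setting fixed. The first 10 kb outside protein-coding genes held 5.65% ± 0.390 against 5.26% (adjusted permutation p = 0.0420), and the next part, from 10 to 100 kb, held 14.4% ± 0.405 against 15.0% (adjusted permutation p = 0.0400). Both differences were under 2 jackknife SE. The first did not pass when any overlap counted (ratio 1.07, adjusted permutation p = 0.0809) or with stretches over 200 kb left out (ratio 1.01, adjusted permutation p = 0.716), and the second turned to 1.01 (adjusted permutation p = 0.478) with no stretch left out of the placement. The gene end share passed with windows of 5 kb (ratio 1.08, permutation p = 0.0020) and with all annotated genes (ratio 1.12, permutation p = 0.0020). With no stretch left out (ratio 1.09) it passed as a single test (permutation p = 0.0398) but not when adjusted over the classes (adjusted permutation p = 0.0597). It was 0.963 (permutation p = 0.418) with stretches over 200 kb left out.

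Close to gene ends the density differed between the inner and the outer side. The first 0.5 kb inside protein-coding genes held 99 peaks against 134 at random, a ratio of 0.74 (95% Poisson interval 0.60 to 0.90, adjusted permutation p = 0.00514). The first 0.5 kb outside held 133 peaks against 97.6, a ratio of 1.36 (95% Poisson interval 1.14 to 1.61, adjusted permutation p = 0.00514). Within genes the ratio was highest between 20 and 100 kb from the nearest end, at 1.32 from 20 to 50 kb and 1.33 from 50 to 100 kb, each with an adjusted permutation p of 0.00514. Deeper than 100 kb it was 1.00. Transcription start and end sites were not told apart in these values, and this profile was added after the data were seen.

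**Figure D1:**
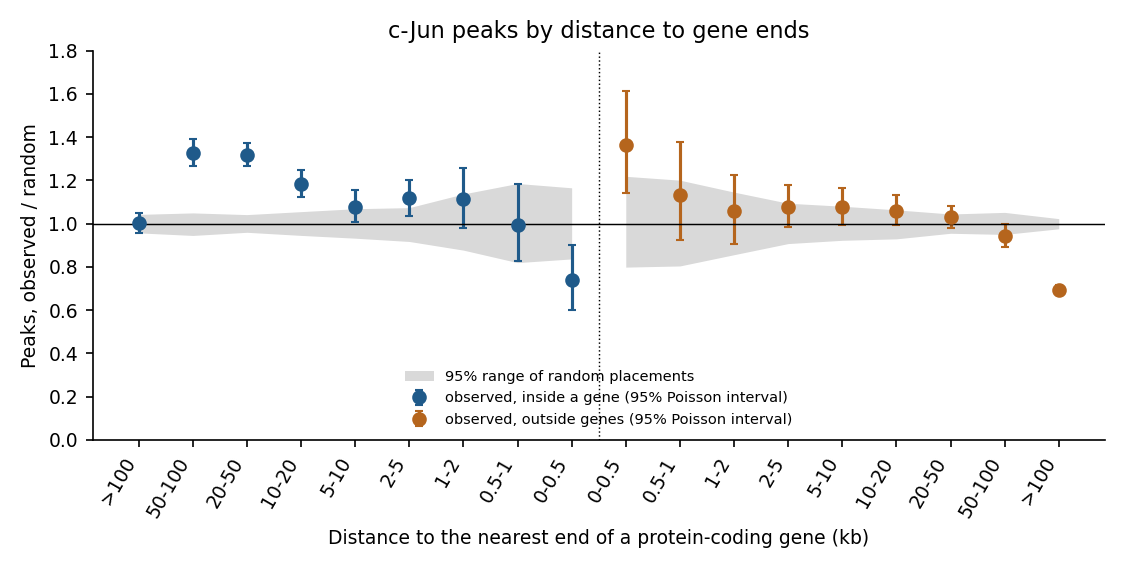
Ratio of observed c-Jun peaks to the mean of 1000 random placements (vertical axis) in bins of distance in kb to the nearest end of a protein-coding gene, for peaks inside genes (left) and outside genes (right). Bars are 95% Poisson intervals and the grey band is the 95% range of the placements; the ratio falls to 0.74 just inside gene ends, reaches 1.33 at 50 to 100 kb inside, and is 0.69 over 100 kb outside.

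Genes of the fibroblast matrix, of the response to YAP and TEAD, and of secreted proteases and cytokines carried c-Jun peaks more often than genes with territories of the same size. At least 1 peak was assigned to 21 of 22 YAP-TEAD response genes, to 28 of 40 matrix and contractile genes and to 19 of 32 protease and inflammatory genes. Matched random lists had 11.4 (95% range 7 to 16), 17.8 (12 to 23) and 9.57 (5 to 14) such genes. These ratios were 1.84, 1.57 and 1.99, with adjusted permutation p of 0.0034, 0.00453 and 0.0034. They were the 3 of 17 lists past an adjusted p of 0.05, and 5 lists passed without adjustment. The random lists were matched on territory, not on position. List members that lie near each other, such as CXCL8 and AREG on chromosome 4, are not independent. The p-values, above all that of the protease and inflammatory list, can thus be too small. Of all 19126 protein-coding genes, 6196, or 32.4%, had a peak.

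Among the YAP-TEAD response genes, known to respond to the co-activator YAP and its DNA-binding partners TEAD, the member without a peak was ARHGEF17. ASAP1 had 14 peaks where its territory and chromosome would give 3.45, CRIM1 had 9 against 2.09, CCDC80 had 7 against 0.943, and NT5E, which encodes the surface enzyme CD73, had 7 against 1.15. The well-known response genes CCN1 and CCN2, encoding matricellular proteins, had 2 and 3 peaks, all outside the gene bodies. CCN1, CCN2 and ARHGEF17 were named after their values were seen. In this list and those below, up to 4 members were named for having the most peaks. That choice by itself favours values above expectation. No gene passed the adjusted threshold in the negative binomial test on peaks per gene. The list as a whole held 88 peaks against 30.8 (95% range 15 to 50) in matched lists. It shares 3 members with the other lists.

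The matrix and contractile genes held 2.28 times as many peaks as matched lists, which had 44.2 (95% range 26 to 65; adjusted permutation p = 0.00085). COL5A2, a chain of fibrillar collagen V, had 12 peaks, all within the gene, against 2.96 expected. COL6A3, of collagen VI, had 8 against 1.60, all in its flanks. LOXL2, an enzyme that cross-links collagen, had 7 against 0.813, and FBN1, which encodes the microfibril protein fibrillin-1, had 7 against 1.92. FN1, encoding fibronectin (chromosome 2, 215360865 to 215436068), had 4 peaks against 1.24, of which 2 were inside the gene, at 215367826 to 215368115 and 215410906 to 215411195. The former also lay inside the overlapping gene ATIC and was assigned to both genes. COL1A1, of collagen I (chromosome 17, 50184101 to 50201631), had 2 peaks against 0.388, at 50218763 to 50219052 and 50219336 to 50219625. These lay close together, 17276.5 and 17849.5 bp from the gene, and may be a single site. A nearer peak, 5.51 kb from COL1A1, was assigned to another gene. Of the 40 members, 12 had no assigned peak. The call for this list ended when peaks were assigned only up to 10 kb from genes (ratio 1.505, adjusted permutation p = 0.0694).

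Of the proteases and inflammatory genes, CXCL8, encoding the chemokine interleukin-8, and MMP13, a collagenase, had 5 peaks each against 0.737 and 0.672. The growth factor gene AREG had 4 against 0.929 and the cytokine gene IL6 had 3 against 0.898. All of these peaks lay outside the gene bodies. The list held 4 genes with a peak within 1 kb of a gene end, one of them IL6, and 13 members had no peak. On peaks within 1 kb of gene ends alone, none of the 17 lists passed an adjusted p of 0.05 in the permutation test. Ratios there were 4.91 for the YAP-TEAD response, 2.96 for matrix and 4.61 for protease and inflammatory genes, from 3, 3 and 4 bound genes. Whether the small counts explain the lost calls was not tested.

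Genes of TGF-beta signalling and immediate early and MAPK feedback genes did not pass on the number of genes with a peak under the main setting, but did on the number of peaks. For the TGF-beta pathway, 22 of 32 genes had a peak against 15.3 (ratio 1.44, adjusted permutation p = 0.0612), and the genes held 81 peaks against 38.9 (adjusted permutation p = 0.00085). The number of TGF-beta genes with a peak passed with peaks assigned only up to 10 kb (ratio 1.56, adjusted permutation p = 0.0280), with peaks outside gene ends (1.47, 0.0493), with no stretch left out (1.44, 0.0490) and with no matching (2.12, 0.00227). SMURF2, a ubiquitin ligase of the pathway, had 10 peaks, LTBP1, a binding protein of latent TGF-beta, 9, TGFBR3, a co-receptor, 7, and SMAD3, a signal transducer, 6. TGFB1 had none. For the immediate early and MAPK feedback genes, 17 of 30 had a peak against 12.4 (ratio 1.37, adjusted permutation p = 0.209), with 68 peaks against 28.3 (adjusted permutation p = 0.00085). With peaks assigned only up to 10 kb from genes, the ratio of bound genes was 2.32 (adjusted permutation p = 0.0147). PHLDA1, the MAPK phosphatase gene DUSP10 and the transcription factor gene KLF6 had 7 peaks each, against 0.829, 1.75 and 1.51. DUSP1, encoding another MAPK phosphatase, had 6 against 0.518.

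Genes of the pluripotent state held fewer peaks than matched genes, but the number of such genes with a peak passed in no setting. A peak was assigned to 8 of 36 genes of the pluripotency list against 13.3 (95% range 8 to 18) in matched lists, a ratio of 0.60 that did not pass (adjusted permutation p = 0.160). The number of peaks, 12 against 32.5 (95% range 17 to 52), did pass (ratio 0.37, adjusted permutation p = 0.0175), and 5 of the 12 were in JARID2, a component of Polycomb repressive complexes. POU5F1, SOX2, NANOG and LIN28A, which encode core pluripotency factors, had no assigned peak. The nearest peak was 75.6 kb from POU5F1, 306.5 kb from SOX2, 61.6 kb from NANOG and 32.7 kb from LIN28A. Their territories would give only 0.422, 1.39, 0.183 and 0.279 peaks, so the absence of a peak is not distinguishable from chance for any of these genes alone. The other bound members, among them KLF17, LEFTY2 and LIN28B, had 1 each.

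The epithelial list, whose genes are switched on when fibroblasts are reprogrammed, had 8 of 28 genes with a peak against 7.72 (ratio 1.04, adjusted permutation p = 1). EPCAM had 2 peaks, CDH1, encoding E-cadherin, had none, and ITGA6, OCLN and ST14 had 4, 3 and 2. Lists for reprogramming barriers (8 of 26 genes against 7.97), the cell cycle (8 of 32 against 8.27) and ribosomal proteins (6 of 46 against 5.81) had adjusted permutation p of 1. With no matching on territory the ribosomal protein ratio turned from 1.03 to 0.402 and passed (adjusted permutation p = 0.0176). In these lists, MACROH2A1 had 4 peaks, CDK6 had 6, and CDKN1A, which encodes the cell cycle inhibitor p21, had 1 peak at chromosome 6, 36667039 to 36667328. NCOR1 and CHAF1B of the barriers, CDC25C, CDKN2B and CCND3 of the cell cycle, and RPL34, RPS12, RPL3 and RPS14 of the ribosomal proteins had 1 or 2 peaks each.

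Lists of genes of other cell types did not pass on the number of genes with a peak, with ratios on either side of 1. For hepatocyte genes, 2 of 24 had a peak against 7.07 (ratio 0.28, adjusted permutation p = 0.0612), which passed with no stretch left out (0.281, adjusted permutation p = 0.0484) and with no matching (0.257, 0.0263). The number of their peaks was also 2, against 13.2 (adjusted permutation p = 0.0136), 1 each for CPS1 and SERPINA1. Neuronal genes had 8 of 23 against 10.9 (adjusted permutation p = 0.436), led by MAP2 and SYT1 with 5 each, SNAP25 with 3 and SLC17A6 with 2. Lung epithelial markers had 4 of 22 against 6.09 (adjusted permutation p = 0.578), namely TP63 with 4 peaks, CAV2 with 2, and HOPX and SFTPB with 1 each. Leukocyte markers had 5 of 24 against 5.67 (adjusted permutation p = 1), led by PTPRC with 3, the other bound members, among them CD68, CSF1R and IKZF1, having 1 each. Endothelial markers had 12 of 22 against 8.74 (ratio 1.37, adjusted permutation p = 0.303), with 5 peaks at FLT1 and 3 each at KDR, PECAM1 and TEK. A site near a marker gene does not show that the cell type was present.

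**Figure D2:**
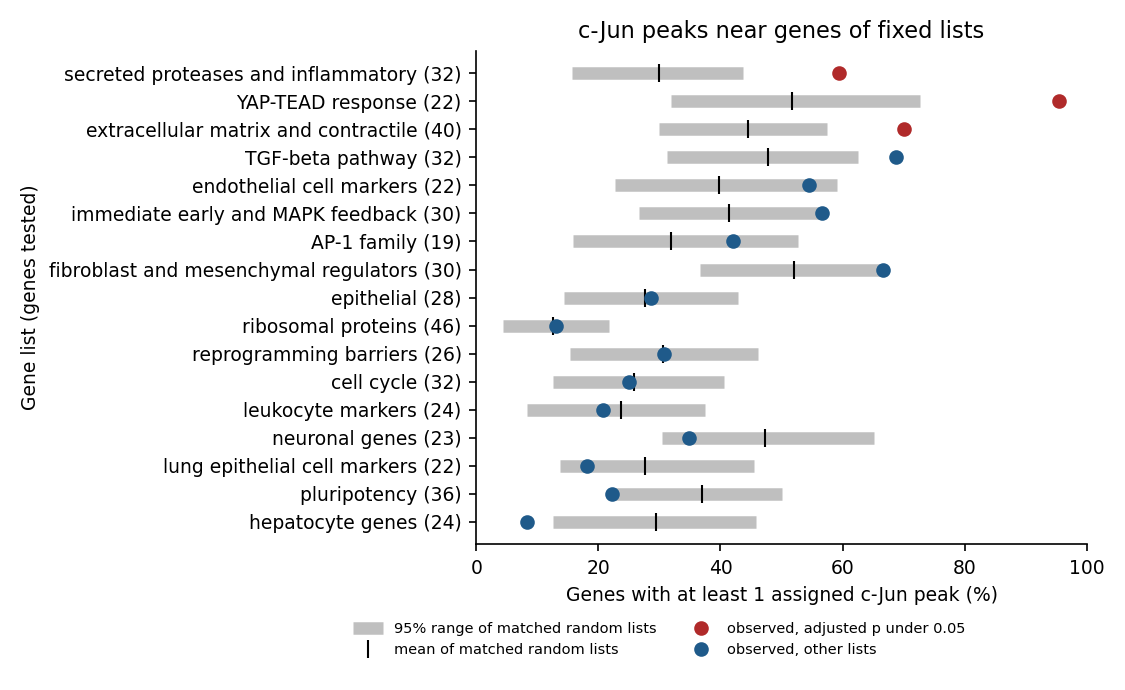
Percentage of genes with at least 1 assigned c-Jun peak (horizontal axis) for 17 fixed gene lists, with the number of genes tested in brackets. Dots are observed values, ticks the mean and grey bars the 95% range of 10000 random lists matched on territory; the 3 red lists, led in percentage by the YAP-TEAD response genes at 95.5%, and the TGF-beta list lie above their ranges and the hepatocyte list below, the last pair without passing the adjusted threshold.

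The fibroblast and mesenchymal regulators had 20 of 30 genes with a peak against 15.6 (ratio 1.28, adjusted permutation p = 0.209), and passed with no matching (2.05, adjusted permutation p = 0.00255) and with peaks given to every gene within 100 kb (1.31, 0.0374). RUNX1 had 10 peaks against 2.19, the regulators NFIB and ZEB2 had 6 each against 3.45 and 1.85, and EBF1 had 5 against 3.78. Of the AP-1 family, 8 of 19 genes had a peak against 6.07 (ratio 1.32, adjusted permutation p = 0.578). The gene of c-Jun itself, JUN (chromosome 1, 58780791 to 58784047), had 5 peaks against 1.04, none in the gene. They lay at 58753969 to 58754258, 58755510 to 58755799, 58764311 to 58764600, 58765110 to 58765399 and 58883269 to 58883558. ATF3 had 5 peaks against 0.848, and ATF2 and JDP2 had 2 each. FOSL2 had a single peak, at chromosome 2, 28392690 to 28392979, whose centre was 23.5 bp outside the gene. JUNB, FOS and FOSL1 had none, with the nearest peak 468, 94.2 and 213 kb away.

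**Figure D3:**
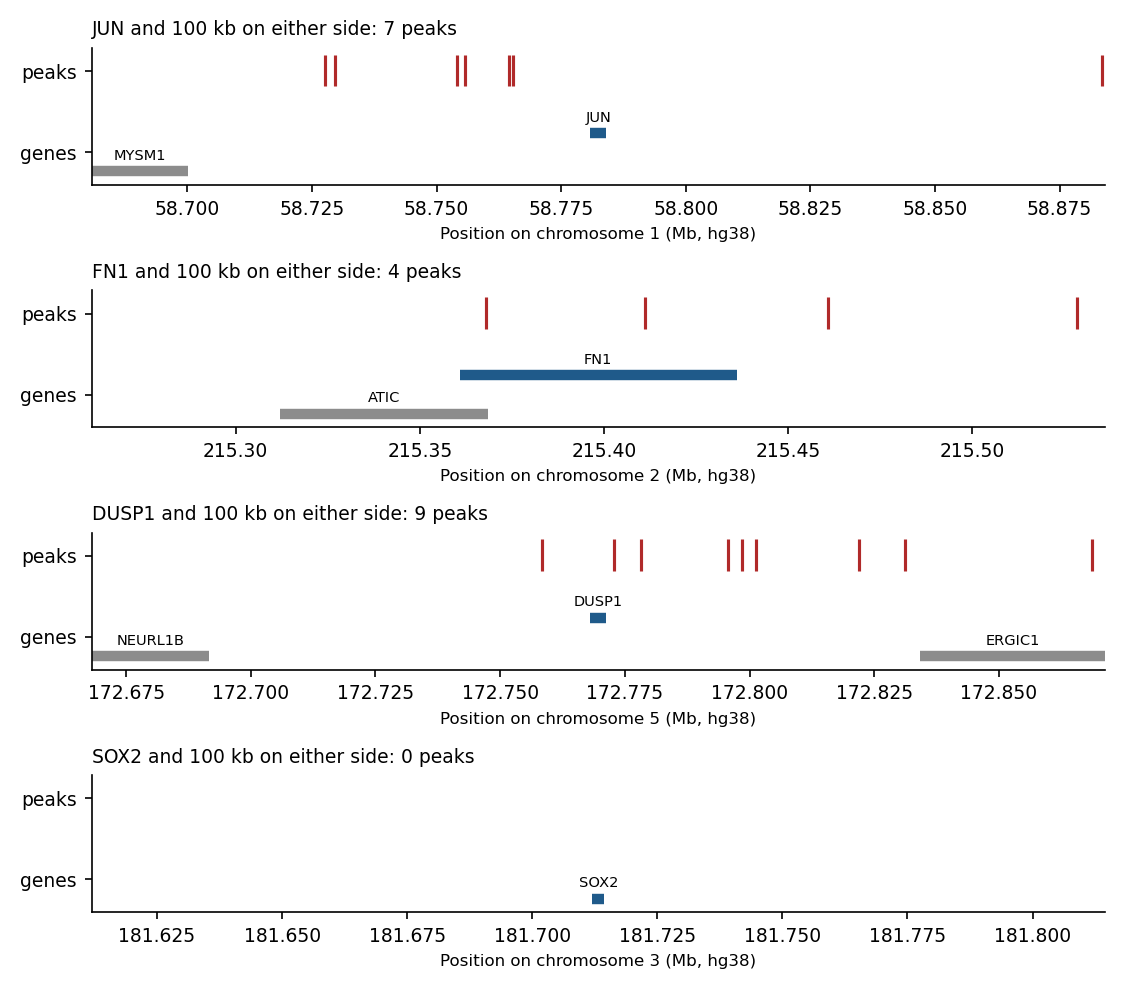
Maps of JUN, FN1, DUSP1 and SOX2 with 100 kb on either side (horizontal axis, position in Mb on hg38), with protein-coding genes as bars and c-Jun peaks as red lines. The windows hold 7, 4, 9 and 0 peaks; a peak nearer to another gene is drawn but not assigned to the gene in the title.

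The genes with the most peaks were long genes. GPC6, encoding a cell surface proteoglycan, had 24 peaks, CAST, encoding the calpain inhibitor calpastatin, 23, the transcription factor gene FOXP1 21, and DST, encoding the cytoskeletal linker dystonin, 20. ATXN1, KCNMA1 and LPP followed with 18 each, PDE4D with 17, EXT1, NRG1, PALLD, PRKG1 and SUGCT with 16, and ARHGAP26, ARID5B, CDH13, DLGAP1, FMN1 and KLF12 with 15. The median territory of the 20 genes with the most peaks was 830 kb, against 55.7 kb over all protein-coding genes. Relative to territory they ranged from 1.46 times the expected number for PDE4D to 6.77 times for ARID5B, which had 15 peaks against 2.22. EXT1 reached 5.53 times, PALLD, an actin-binding protein gene, 5.41 times and DST 4.97 times. None of the 19126 genes passed an adjusted p of 0.05 in the negative binomial test on peaks per gene (dispersion 0.811), while 627 had an unadjusted p under 0.05. Those 627 are less than a share of 0.05 of all genes, so their number is no excess over chance. The dispersion was fitted to these same counts, which limits what the test can find. In all, 778 genes had 5 or more peaks and 120 had 10 or more, and 3407 peaks lay over 100 kb from every protein-coding gene.

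Peaks were grouped along the chromosomes. Of neighbouring pairs, 18.5% ± 0.364 (jackknife SE) lay within 12 kb, against 7.81% at random (95% range 7.44 to 8.21), a ratio of 2.37 and a permutation p of 0.0020, the smallest that the placements can give. Joining across gaps of up to 12 kb gave 33 clusters of 5 or more peaks, where random placements gave 0.667 on average and at most 7. These 33 clusters held 180 peaks, 0.996% of all, and 67.4% of peaks had no neighbour within 12 kb. The largest cluster, at chromosome 6, 16712890 to 16763043, held 8 peaks over 50.2 kb and overlapped ATXN1; the largest in any placement held 7. Clusters of 7 peaks lay at chromosome 15, 63476247 to 63514993, overlapping USP3, at chromosome 5, 124621860 to 124656266, overlapping ZNF608, at chromosome 11, 122167101 to 122208475, 50.9 kb from BLID, and at chromosome 14, 100975661 to 101001519, 4.32 kb from the uncharacterised gene LOC124903407. Clusters of 6 peaks were 2.85 kb from PRKCH, within FMN1, 416 kb from SPRY1 and 128 kb from HS3ST3A1. The tenth cluster by the fixed order, of 5 peaks, overlapped IL1R1, which encodes an interleukin-1 receptor.

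Peak density differed between autosomes. It ranged from 3.09 peaks per Mb on chromosome 19 (95% Poisson interval 2.64 to 3.59) to 7.62 on chromosome 12 (7.15 to 8.11) and 7.61 on chromosome 6 (7.20 to 8.04). The counts departed from those expected by length (chi-square 278 with 21 degrees of freedom, p = 9.15e-47). Chromosomes 16 and 22 were also low, at 4.73 (4.27 to 5.24) and 4.83 (4.16 to 5.58). In a relation looked at after the data were seen, density over the 22 autosomes went with the number of protein-coding genes per Mb by Pearson's r of -0.68 (permutation p = 0.00511, adjusted 0.0153) but not by Spearman's rho of -0.25 (permutation p = 0.255). Without chromosomes 17 and 19, the 2 farthest from the median gene density, r was -0.43 (permutation p = 0.0598, adjusted 0.0897 over the 3 coefficients). Without chromosome 17 alone r was -0.75 (unadjusted permutation p = 0.00173), and without chromosome 19 alone it was -0.27 (unadjusted permutation p = 0.227), so the relation rested on chromosome 19. Autosomes are not replicates, and the peaks of a chromosome are not independent.

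**Figure D4:**
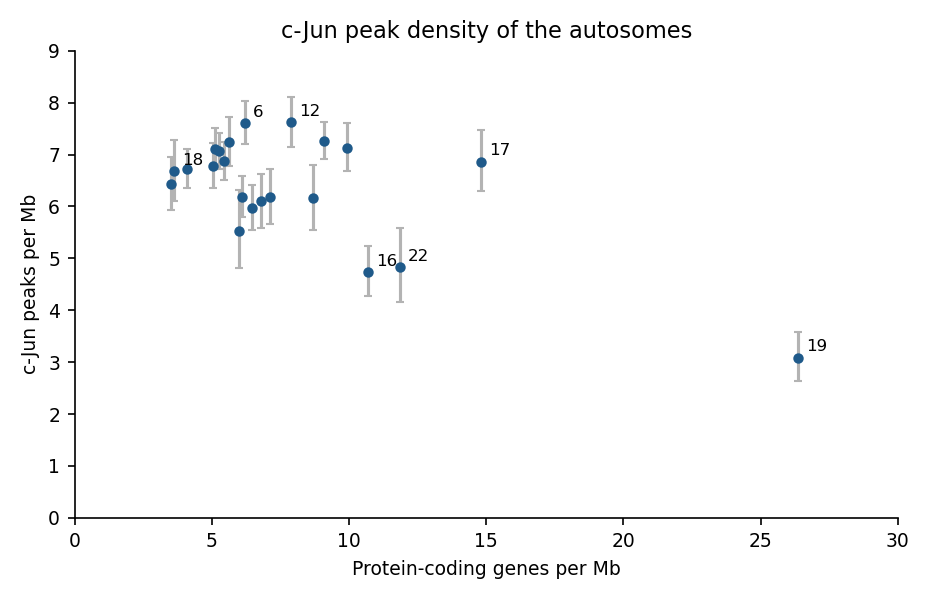
c-Jun peaks per Mb (vertical axis) against protein-coding genes per Mb (horizontal axis) for the 22 autosomes, with 95% Poisson intervals as bars and some chromosomes numbered. Chromosome 19, with 26.3 genes per Mb, has the lowest density at 3.09 peaks per Mb.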

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

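The settings for stretches left out of random placement and the correlations with gene density, with or without chromosomes 17 and 19, were chosen after the data were seen. So were the negative binomial test and the profile of distances to gene ends. The other settings, the other main tests and the gene lists were fixed before the data were examined, with gene ends and bodies in place of 5' ends. Of 210 alternative values, 154 kept their direction and side of the threshold, 27 changed direction, 19 passed the threshold anew, 6 no longer passed and 4 counts of called lists moved by over 1.5 times. Of the changes of direction, 22 were in lists that passed under neither setting. The cause of these changes was not tested. The call was kept in 9 of 10 settings for the YAP-TEAD response and the secreted protease and inflammatory genes and in 8 of 10 for the matrix and contractile genes. Grouping of peaks passed in every setting run, with ratios of 1.60 to 2.88.

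The gene end share passed the threshold with a ratio of 1.08 with windows of 5 kb, 1.12 with all annotated genes and 1.09 with no stretch left out. The last did not pass when adjusted over the classes. The share was 0.963 with stretches over 200 kb left out, where the class within 1 kb of an end also had 0.963. With stretches over 200 kb left out, other annotated genes had 0.902, which passed, and the first 10 kb outside genes 1.01, which no longer passed. That setting lowers the ratio inside genes by construction. With no stretch left out, other annotated genes had 1.03 and the part from 10 to 100 kb 1.01. With any overlap, the first 10 kb had 1.07, which no longer passed.

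The count of called lists, 3, became 8 with no matching, 7 by number of peaks, 5 with no stretch left out and 0 for peaks within 1 kb of a gene end. Ratios for the lists follow; of those given, the TGF-beta, immediate early, fibroblast regulator, hepatocyte and pluripotency lists passed in the settings named, as did the ribosomal proteins with no matching. At 10 kb they were 1.56 for the TGF-beta pathway, 1.12 for the cell cycle, 0.925 for epithelial genes, 1.505 for matrix genes, 2.32 for immediate early genes, 0.676 for reprogramming barriers and 0.941 for ribosomal proteins. At 50 kb they were 1.03 for the cell cycle, 1.66 for immediate early genes and 0.987 for ribosomal proteins, and at the longest distance tried 0.977 for ribosomal proteins. With every gene within 100 kb, they were 0.976 for the AP-1 family, 1.02 for the cell cycle, 0.806 for epithelial genes, 1.31 for fibroblast regulators and 0.873 for reprogramming barriers. With no matching, they were 2.12 for the TGF-beta pathway, 0.884 for epithelial genes, 2.05 for fibroblast regulators, 0.257 for hepatocyte genes, 1.75 for immediate early genes, 1.08 for neuronal genes, 0.945 for reprogramming barriers and 0.402 for ribosomal proteins. By number of peaks, they were 2.09 for the TGF-beta pathway, 1.03 for the cell cycle, 0.151 for hepatocyte genes, 2.40 for immediate early genes, 0.370 for pluripotency genes, 0.625 for reprogramming barriers and 0.945 for ribosomal proteins. With no stretch left out, they were 1.44 for the TGF-beta pathway and 0.281 for hepatocyte genes. For peaks outside gene ends, they were 1.47 for the TGF-beta pathway and 1.01 for the cell cycle. For peaks within 1 kb of a gene end, they were 4.91 for YAP-TEAD response, 2.96 for matrix and 4.61 for protease and inflammatory genes, 1.23 for the cell cycle, 0 for epithelial, 1.86 for leukocyte and 1.59 for neuronal genes.

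No paired analysis was possible because the replicate numbers that the groups share belong to no column of the peak list, and leaving out a replicate gives no value. Not run were the alternatives fixed beforehand that need a sequence, strand, transcripts, repeats, a score or varying peak widths, and the overlap of at least 50% of a peak. Depth is unknown and limits which sites were listed.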

Other observations

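The comparisons with ribosomal protein and cell cycle genes and between the matrix and pluripotency lists, and the choice of single genes below, were made after the results were seen. Some gene families held fewer genes with a c-Jun peak than matched genes. Among 262 families of at least 10 genes formed by symbol stem, 5 passed an adjusted p of 0.05 against random lists matched on territory, all with fewer bound genes. Odorant receptor genes (OR) had 24 of 391 genes with a peak against 67.0, zinc finger genes (ZNF) 78 of 505 against 143, and UGT genes, for glucuronosyltransferases, 2 of 22 against 9.54. Protocadherin alpha genes (PCDHA) had 0 of 13 against 8.23, and genes with only a LOC number 79 of 630 against 142. Adjusted permutation p was 0.0314 for UGT and 0.0131 for the rest. Other large families did not pass. SLC had 133 of 372 genes against 129 and TMEM 59 of 226 against 61.3 (adjusted permutation p = 1 each), while FAM, with 44 of 174 against 55.6 (95% range 45 to 66, adjusted permutation p = 0.555), and RNF, with 35 of 83 against 25.7 (19 to 33, adjusted permutation p = 0.351), lay outside their ranges before adjustment. The LOC genes share only a style of name. The random lists were not matched on chromosome, and 262 zinc finger genes lie on chromosome 19, the autosome with the lowest peak density. The low count of bound ZNF genes was not separated from the low density of that chromosome. Odorant receptor, zinc finger, PCDHA and UGT genes are known to lie in clusters of similar sequence, so their members are not independent. Members whose bodies overlap hold or lack the same peaks, yet the permutation counts each as a separate gene. Their p-values can thus be too small. How reads mapping to several places were treated is not given in the sources used here. TNFRSF genes, with 11 of 21 against 5.21 (adjusted permutation p = 0.122), and MMP genes, with 13 of 25 against 6.94 (adjusted permutation p = 0.225), did not pass.

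Among single genes, TNFRSF12A, which encodes the receptor of the cytokine TWEAK, had 3 peaks in a territory of 3.23 kb where 0.0153 were expected (negative binomial test, adjusted p = 0.0519). MRTFA, a co-activator of serum response factor, had 10 peaks, all inside the gene, against 1.20, and BASP1 had 14 against 1.85. BPGM had 7 against 0.508 and BLID had 13 against 1.43. None of these passed the adjusted threshold. The bound share minus that of matched genes was 40.4 percentage points higher for the matrix and contractile list than for the pluripotency list. This pair was chosen from these values, so no test of the difference is given.

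The YAP-TEAD response list stood above matched lists, and 3 technical explanations were looked at. Of its members in no other list, 18 of 19 had a peak against 9.76 (95% range 6 to 14); with 21 of 22 bound and 3 shared this follows from the count itself and is no separate test. Counting peaks inside gene bodies, 11 of 22 members were bound against 6.87 (95% range 4 to 10, unadjusted permutation p = 0.0286), just above the range. Peaks in the flanks are thus not the whole of the pattern but may account for part. A peak inside a body can still belong to another gene, so this count cannot exclude neighbouring genes. Ribosomal protein and cell cycle genes had 14 of 78 bound against 14.2, within the 95% range of 8 to 20. No excess was thus seen at these genes as a set. Expression was not measured here, and cell cycle genes need not be active in every cell. The count therefore cannot decide whether active genes in general draw peaks. The YAP-TEAD share minus that of matched genes lay 43.7 percentage points above theirs, a value that restates the pattern. Open chromatin at genes active in fibroblasts, and binding with TEAD at shared sites, were not tested here and stay open.

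Peaks were grouped within 12 kb more than random placement gives. After joining peaks within 1 kb, which left 17656, the share was 16.6% against a 95% range of 7.28 to 8.05%, so one site listed as several intervals is not the whole cause. Placements that kept the number of peaks in every 1 Mb window gave 10.7% (95% range 10.3 to 11.1) against 18.5% observed, so broad differences in density account for part at most. Finer differences in mappability or accessibility could not be tested without a sequence or an input track, and no biological explanation was tested.

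Chromosome 19 had the lowest density of the autosomes. Its peaks were 0.533 of those expected from 1 Mb windows elsewhere in the same broad bins of gene count (95% bootstrap interval 0.426 to 0.657). The highest bin, of 31 or more genes, has no upper bound, so gene counts are matched only roughly there. In the bin of 21 to 30 genes, chromosome 19 had 3.81 peaks per Mb against 5.59 elsewhere, and it was lower in every bin it had windows in. These values argue against gene density as the whole cause. Outside zinc finger genes, of which it holds 262, and 25 kb around them, its density was 0.538 of that of the other autosomes (95% bootstrap interval 0.429 to 0.648), so these clusters are not the whole cause either. GC content, repeats and copy number were not tested and stay open, and no biological explanation was tested.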
